A study of Zea mays with 14 samples.

How the data were processed

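Messenger RNA was sequenced from maize seedlings aged 3 days, in 14 libraries that fall into 7 groups of 2. Per the labels' protocols, hairs were scraped from roots frozen in liquid nitrogen, and the root samples are what remained. In the zmlrl5 set, the titles of the wild type root samples say that hairs were removed, and those of the zmlrl5 root samples do not. 6 libraries form a tissue set from the inbred line B73, with root hair, root and aerial seedling. The other 8 form a zmlrl5 set, with wild type and zmlrl5 root hair labelled W22, and wild type and zmlrl5 root labelled B73. The labels call the root hair mutant a knock down and the root mutant a knock out. The growth protocol names B73 for every sample while the cultivar label gives W22 for the 4 root hair libraries of the zmlrl5 set, and W22 was taken from the cultivar label. Per the labels' protocols RNA was extracted with TRIzol, whereas the series design text names a Qiagen kit. Libraries were made with a NEBNext mRNA kit, and the series design text names a HiSeq2500.

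The deposited files hold raw counts of reads per gene for 39305 gene IDs, as whole numbers whose totals differ between libraries. Per the submitters' processing notes, TopHat2, HTSeq and DESeq were used, without versions. The genome build, the strand setting and the role of each tool are not given in the sources used here, so counts of overlapping or antisense genes may hold reads of each other, and reads shared between close copies of a gene may be split or lost. In the tissue set, HTSeq's summary entries gave 3.58% to 6.71% of reads outside genes and 1.91% to 2.58% of ambiguous reads, which stayed out of library sizes and tests. The files of the zmlrl5 set hold no such entries.

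Totals ran from 12336633 to 27788359 counts per library. The floor of 3 counts equals 0.108 to 0.243 CPM (counts scaled to a common library size), and 2779 IDs had no read in any library. Where a group had 0 counts, a fold was given as a lower bound against 3 counts over the group. With 1 to 3 counts, the ratio was given with an exact Poisson interval at 95% confidence. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Whether the 2 libraries of a group come from separate plants or pools is not given in the sources used here, so p-values measure the spread between these samples.

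Counts were tested with edgeR 4.0.16 in R 4.3.3. Each set was filtered with filterByExpr at its minimum count of 10 and minimum total of 15, scaled by TMM, and fitted by quasi-likelihood (glmQLFit and glmQLFTest, two-sided) with group means and no covariate. Adjusted p-values are Benjamini-Hochberg adjusted over the genes tested in a comparison, and a gene was called at adjusted p under 0.05. Calls with an absolute log2 fold change of at least 1 were counted as well. The standard error (SE) of a log2 fold change was its absolute value divided by the square root of F. CPM values in sentences use the TMM factors of the set's own fit and are means ± SD of 2 libraries. The difference between the mutant effects was tested as an interaction contrast. Comparisons across the sets used a fit of all 14 libraries. Overlaps of calls were tested with Fisher's exact test, two-sided, over the genes tested in both comparisons. It counts genes as independent, which they are not, so its p-values and intervals do not measure the spread between libraries.

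Gene names came from a RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, which holds no descriptions. It matched 18996 IDs, 18475 of them once and 521 more than once, and named 2696. rth3 was paired by that table, while GRMZM2G099056, GRMZM2G426953 and GRMZM2G436299 were taken as rth1, rth5 and rth6 from a list of IDs. 33 gene lists were defined by patterns of names, of which 21 had 5 or more members and 1 had none. Apart from the roothairless list, they hold only genes with a name, which 2264 of 25551 genes tested in the tissue set had. The counts of a list therefore cover the named part of a family, not the whole family. Some members match by name only: fer1 is a ferritin in the receptor kinase list, and bHLH7 and bHLH84 carry maize numbers that do not show the family of their lists. Lists with 5 or more tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists of a comparison. With a correlation estimated from the data in place of the preset value, 0 lists were called in any comparison. That option also tests on the few residual degrees of freedom of the fit. In root hair against root, DNA replication, auxin and potassium transporter genes had estimates of -0.08, -0.01 and 0.00, below the preset value, and still lost their calls. The lost calls therefore do not show that correlation between genes undoes a list's result.

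The groups, comparisons, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule takes, per comparison, the 4 roothairless genes and the LRL-type bHLH list, then the 5 called genes with a name that rose most and the 5 that fell most at 20 CPM or more in the higher group with replicates that do not overlap. Then come up to 2 called members per list with the largest change at 5 CPM or more, until 30 genes are reached. Other list members named beside a list's counts were chosen after their values were seen, as examples.

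The tests were checked on simulated counts drawn from the real means and library sizes, with 200 changed genes per comparison. The changed genes were taken from those at a mean of 5 CPM or more, and nearly all others were left unchanged. The rates of recovery therefore do not cover genes near the floor or comparisons in which most genes differ. Changes of 4-fold were recovered at 100% for root hair against root and for both comparisons of zmlrl5 with wild type. Changes of 2-fold were recovered at 61% for root hair against root in a fit of 25551 genes. For zmlrl5 root hair and zmlrl5 root they were recovered at 95% and 99%, in fits of 25303 genes. Of unchanged genes, 7 to 24 were called per comparison, and 0 of 20 unchanged lists were called.

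Alternatives were DESeq2's size factors and upper-quartile scaling in place of TMM, no filter, a filter of 1 CPM in 2 libraries, the Wald test of DESeq2 1.42.0, a replicate block, each library left out in turn, all 14 libraries in 1 fit, only the libraries compared, both sets of wild type B73 root libraries, and fry or an estimated correlation for lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.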

Results

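Transcripts of maize seedlings aged 3 days were counted in 14 libraries, 2 in each of 7 groups. In the inbred line B73 the groups were root hair, root without its hairs, and aerial seedling. A further 4 groups set zmlrl5 plants against wild type, in root hair of the inbred line W22 and in root of B73. The name zmlrl5 points to the LRL group of bHLH transcription factors, which promote root hair growth in other plants. Total counts were 25845354 and 27788359 in B73 root hair, 14775951 and 26147759 in B73 root, and 20731338 and 17774420 in aerial seedling. In the zmlrl5 set they were 17731689 and 24177435 in W22 wild type root hair, 19319441 and 16626955 in W22 zmlrl5 root hair, 12336633 and 17548079 in B73 wild type root, and 21110577 and 18522039 in B73 zmlrl5 root. The Pearson correlation of log2 CPM across genes, which are not independent replicates, was 0.980 to 0.990 between the 2 libraries of a group. It was 0.700 between B73 root hair and B73 root, and 0.546 between B73 root hair and aerial seedling.

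**Figure D1:**
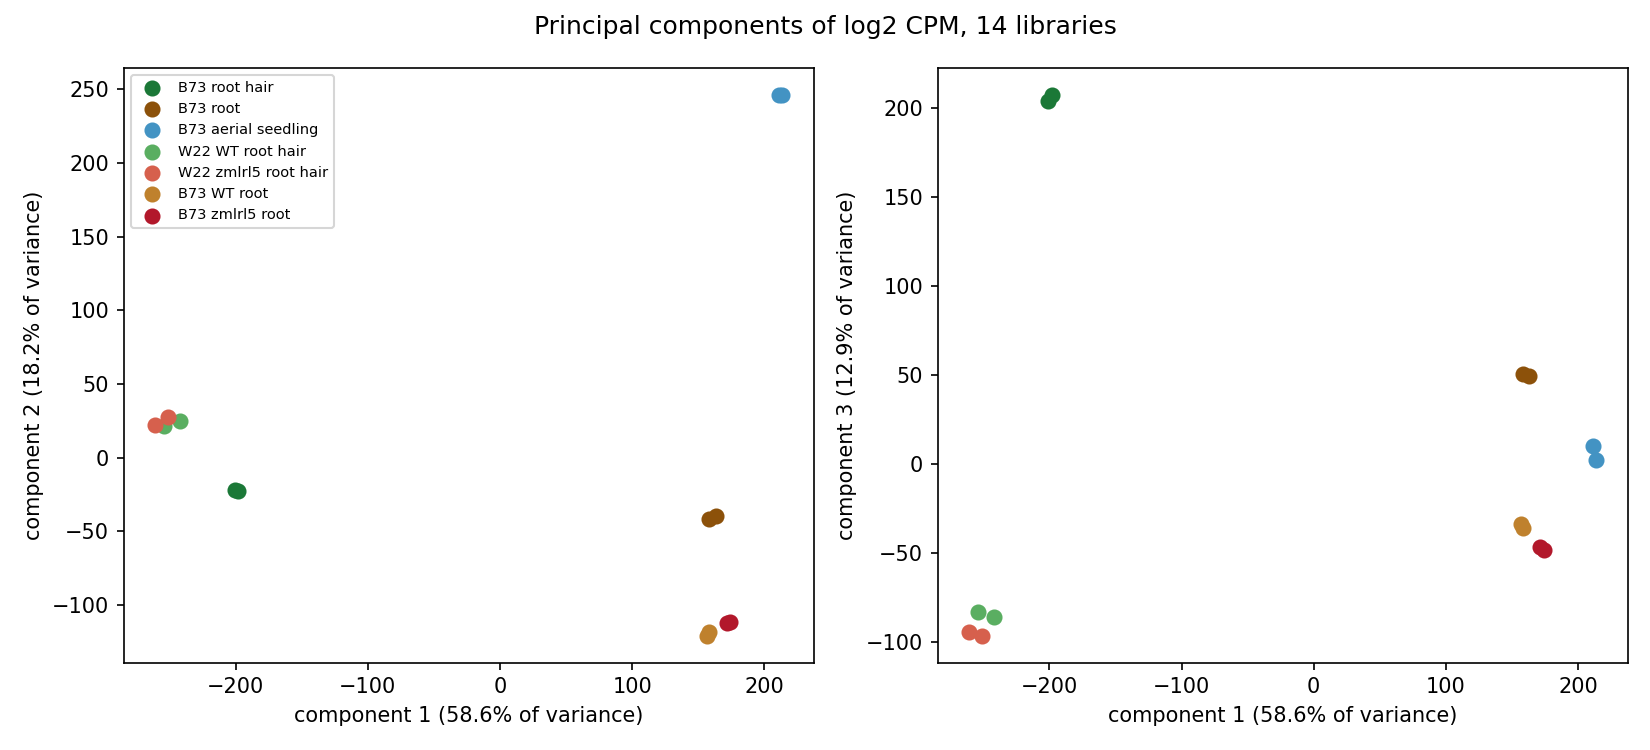
Principal components of log2 CPM of the 14 libraries, 1 point per library, with component 1 on the horizontal axes and component 2 (left) or 3 (right) on the vertical axes, in units of log2 CPM. Component 1, with 58.6% of the variance, parts the 6 root hair libraries from the other 8.

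Root hair of B73 was compared with the root it had been scraped from, which asks which transcripts mark the hair cells. The roothairless genes, whose mutants have short or missing hairs, were mostly higher in root hair, 3 of 4. rth3 (GRMZM2G377215), which encodes a COBRA-like wall protein, stood at 377 ± 57.7 CPM in root hair and 20.4 ± 0.648 CPM in root (SD, n = 2), a log2 fold change of 4.21 ± 0.25 (SE, adjusted p = 1.86e-17). GRMZM2G426953, listed as rth5, an NADPH oxidase gene, rose by 4.08 ± 0.27 on the log2 scale, and GRMZM2G436299, listed as rth6, a cellulose synthase-like gene, by 5.33 ± 0.27. GRMZM2G099056, listed as rth1, an exocyst gene, differed by 0.26 ± 0.26 (adjusted p = 0.387). The cellulase gene Cel4 reached 5061 ± 489 CPM in root hair and 28.6 ± 4.79 CPM in root (SD, n = 2).

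Of 25551 genes tested with edgeR's quasi-likelihood test, 8678 were higher and 10007 lower in root hair, and 6991 and 9229 of them changed 2-fold or more. Among the largest rises were the hemoglobin gene Hb2 with a log2 fold change of 8.93 ± 0.39, and ABP1 and ABP2, actin-depolymerizing factor genes, with 7.54 ± 0.42 and 7.36 ± 0.33. The aquaporin gene TIP4-3 had 1 count in root, and its ratio was 1417 (95% counting interval 254 to 56017). On the other side, LOL3 fell by 9.83 and grp3, a glycine-rich protein gene, by 8.59 on the log2 scale. Few root hair counts fell on the laccase gene Lac1 (3 counts, ratio of root to root hair 1164, interval 398 to 5644), the auxin carrier gene aic1 (2 counts, ratio 429, interval 119 to 3545) and permease (1 count, ratio 743, interval 133 to 29370). bHLH7 (GRMZM2G042920), the only member of the LRL-type bHLH list and placed there by its maize number alone, fell by 2.81 on the log2 scale (adjusted p = 9.66e-06).

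Of 12 expansin genes, which loosen walls, 0 were higher and 11 lower: expB5 had 0 counts in root hair and 701 in root, expa2 had 1 root hair count (ratio of root to root hair 519, interval 92.9 to 20519), and expB2 and expB4 fell by 7.46 and 7.07 on the log2 scale. The list passed camera's test (adjusted p = 0.00017, and adjusted p = 0.352 with an estimated correlation). Both IDs named HRGP, a hydroxyproline-rich wall protein, were lower, GRMZM2G168651 by -6.80 and GRMZM2G099780 by -2.27. Cellulose synthase genes and their relatives were lower for 7 and higher for 2 of 10 members, with CesA12 at -7.77 and CSLD1 at -7.75 (camera adjusted p = 0.0643, and 0.497 with an estimated correlation). The wall enzyme gene xth1 at -7.78 and AGP2 at -4.42 were lower, while C5, the only tested member of the pectin enzyme list, was higher at 1.19 CPM against 0 in root. Of the 9 named ROP signalling and NADPH oxidase genes, 4 were higher, rbohB at 2.57 and rop2 at 1.17 among them. Another 4 were lower, with rop3 at -5.50 and rop6 at -4.74. GRMZM2G426953 and GRMZM2G436299, both higher, have no name in the table of names and enter neither this list nor the cellulose synthase list. The actin gene Maz95 was higher at 2.50 and Maz83 lower at -2.74, in a list of actin and vesicle traffic with 3 higher and 4 lower of 12 (camera adjusted p = 0.884, as for the ROP list). Class III peroxidase genes were higher for 2 and lower for 4 of 6 (adjusted p = 0.412), with PER70 at -7.25 and PER42 at -6.77, and fer1, a ferritin gene, was higher at 1.62.

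Members named beside the counts of lists, unless the rule for named genes took them, were chosen after their values were seen. Potassium transporter and channel genes were higher for 13 and lower for 3 of 19 members, with HAK24 at 3.92 ± 0.27 and HAK1 at 3.42 ± 0.24 (adjusted p = 0.0283 by camera, and adjusted p = 0.352 with an estimated correlation). Of 4 tested phosphate transporter genes, 2 were higher, pht9 by 3.96 ± 0.26 and pht2 by 2.01 ± 0.24, and 1 was lower. Genes of dividing cells were lower: 12 of 13 DNA replication genes, with pcna2 at -8.50 and MCM6 at -6.96, and 9 of 9 core histone genes, with his2b5 at -8.08. Both lists had adjusted p = 0.0007 by camera, and adjusted p = 0.251 and 0.352 with an estimated correlation. Auxin genes were lower for 29 and higher for 8 of 43 members, and ribosomal protein genes lower for 22 and higher for 3 of 28, with rpl30 at -4.21 and rps24 at -3.51. These lists had adjusted p = 0.00211 by camera, and adjusted p = 0.251 and 0.74 with an estimated correlation. Benzoxazinoid genes, which make defence compounds, were lower for 7 of 9 (bx1 at -7.08, BX3 at -7.01) and higher for 2, with BX14 at 1.67 (adjusted p = 0.0308, and 0.352 with an estimated correlation). Lignin pathway genes were lower for 12 and higher for 4 of 19, with PAL1 at 2.91 and BM1 at 3.80 among the higher (adjusted p = 0.0291, and 0.352 with an estimated correlation). Photosynthesis genes were higher for 12 and lower for 2 of 17 at low levels, with Cab-m7 at 3.62 CPM in root hair and 0.518 CPM in root (adjusted p = 0.0128, and 0.352 with an estimated correlation). Adjusted over the list alone, these counts were the same except for 23 ribosomal genes lower. The median log2 fold change of all genes was -0.14 with TMM, -0.21 with DESeq2's size factors and -0.46 with upper-quartile scaling. The lists named here kept the sign of their tests under these scalings.

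**Figure D2:**
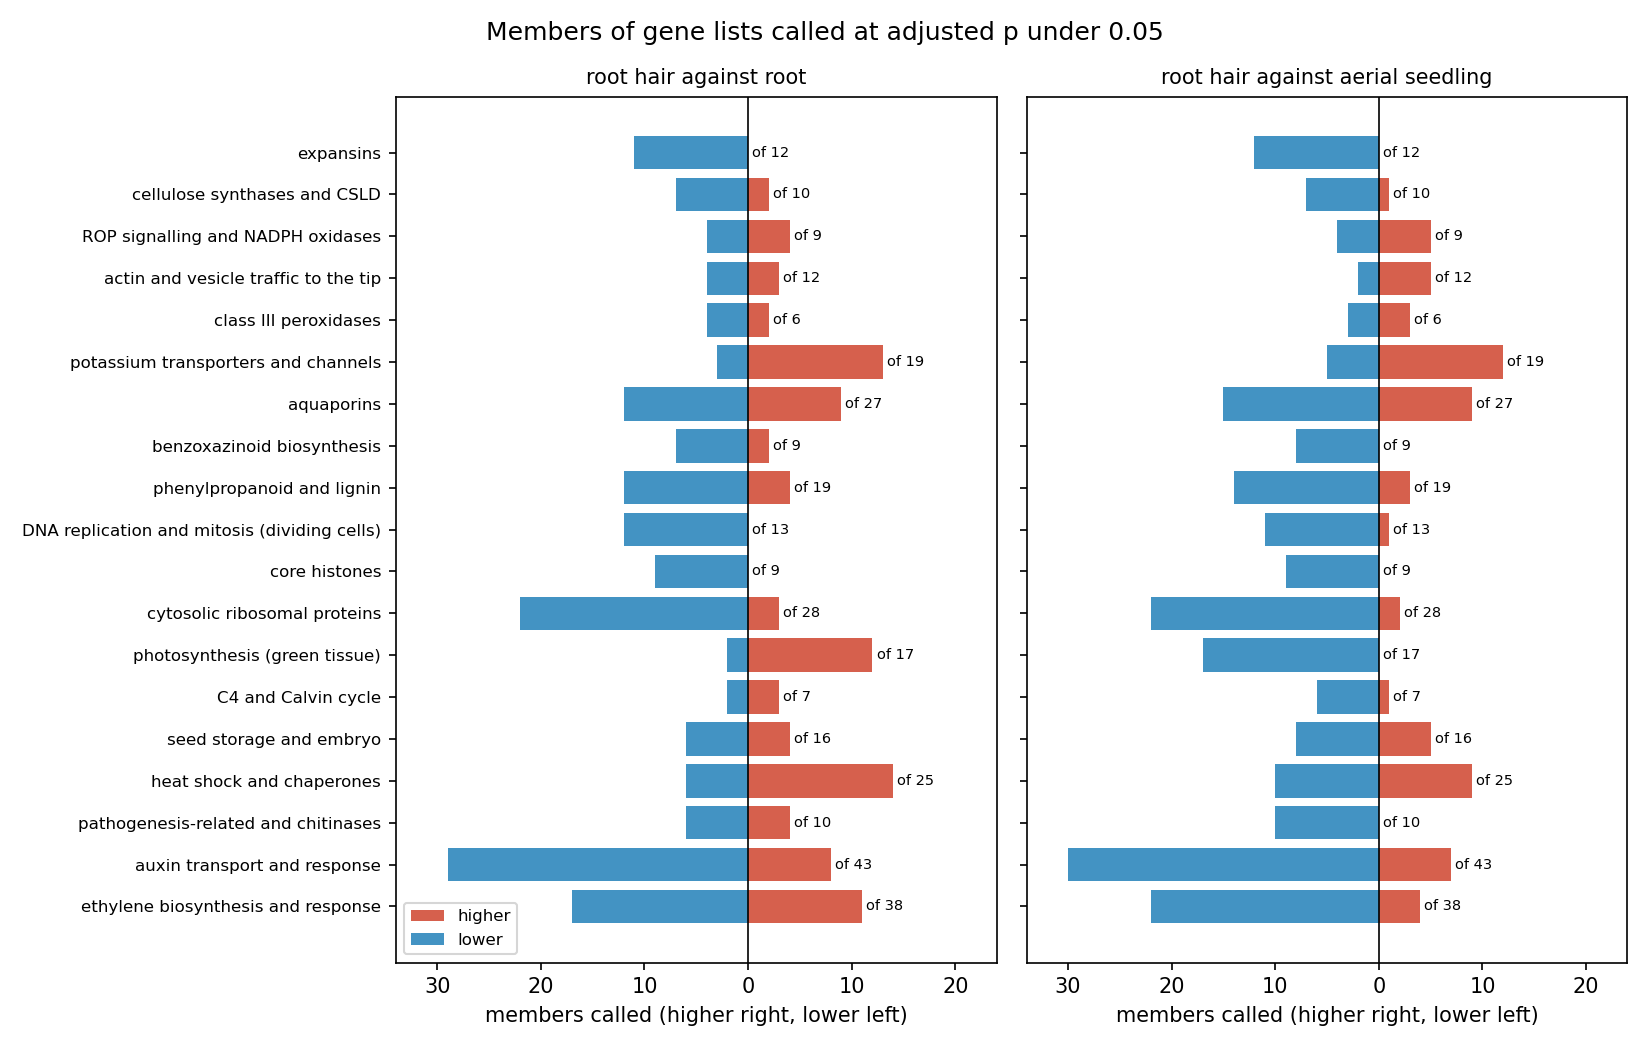
Numbers of members of gene lists (horizontal axis, number of genes) called higher (right) or lower (left) in B73 root hair against root and against aerial seedling, by edgeR's quasi-likelihood test at adjusted p under 0.05. Expansins have 0 members higher in either comparison, 11 of 12 lower against root and 12 of 12 lower against aerial seedling.

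Root hair was also compared with the aerial seedling, which parts transcripts of hair cells from those of the shoot. All 4 roothairless genes were higher in root hair, with log2 fold changes of 3.87 ± 0.24 for rth3, 4.95 ± 0.28 for GRMZM2G426953 and 6.87 ± 0.30 for GRMZM2G436299 (SE, n = 2 per group). GRMZM2G099056 stood at 30.6 ± 0.751 and 10.8 ± 5.08 CPM (SD, adjusted p = 7.02e-06). The peroxidase gene PER2 stood at 3358 ± 9.46 CPM in root hair and 1.16 ± 0.367 CPM in aerial seedling. Cel4 was higher by 13.13 ± 0.38. Of 25551 genes tested, edgeR's quasi-likelihood test called 8735 higher and 11502 lower in root hair, 7301 and 10667 of them by 2-fold or more.

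ABP2 was at least 1439-fold higher in root hair, IPT4, a cytokinin synthesis gene, at least 564-fold and the root cap gene RCP1 at least 342-fold. pht9 had 2 counts in aerial seedling, a ratio of 4259 (interval 1179 to 35175). At 0 counts in root hair, the glucanase gene geb1 was at least 2303-fold lower, gar2 at least 1456-fold and the auxin efflux gene PIN10a at least 984-fold. plt2 and kin1 were lower at -13.63 and -13.37. bHLH7 fell by 4.10 and bHLH84 had 1 count in root hair (ratio of aerial seedling to root hair 311, interval 55.5 to 12322). Among wall genes, expB5 was at least 83.2-fold lower, expB8 went from 472 CPM in aerial seedling to 0.455 CPM in root hair, and log2 fold changes were -7.23 and -1.62 for the HRGP IDs, -7.94 for CSLD1, -6.14 for CesA-3, -8.00 for Agp2 (a starch synthesis gene by its other name) and -6.75 for AGP2. rop6 at -3.68 and the actin gene ACT-1 at -3.20 were lower, while rbohB at 3.36, the profilin gene PRO4 at 3.15 and fer1 at 1.28 were higher. ROP and NADPH oxidase genes were higher for 5 and lower for 4 of 9, actin and vesicle traffic genes for 5 and 2 of 12, and cellulose synthase genes for 1 and 7 of 10 (camera adjusted p = 0.601, 0.304 and 0.074).

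By list, 17 of 17 photosynthesis genes were lower in root hair, with Cab-m7 at -7.67 and rbcS-m3 at -8.44 (camera adjusted p = 6.06e-05, and 0.314 with an estimated correlation). All 12 expansins were lower (adjusted p = 6.93e-05, and 0.364 with an estimated correlation), and so were all 10 pathogenesis-related and chitinase genes, such as chn1 at -6.99 and PR10 at -2.81 (adjusted p = 0.00104, and 0.364 with an estimated correlation). Benzoxazinoid genes were lower for 8 of 9, with bx2 at -10.90 and bx1 at -9.60, and core histones for 9 of 9 (adjusted p = 0.003 each, and 0.314 and 0.39 with an estimated correlation). Auxin genes were lower for 30 and higher for 7 of 43 (adjusted p = 0.00633), and DNA replication genes lower for 11 and higher for 1 of 13 (adjusted p = 0.0161), with adjusted p = 0.314 for each with an estimated correlation. Ribosomal protein genes were lower for 22 and higher for 2 of 28, lignin genes for 14 and 3 of 19, C4 cycle genes for 6 and 1 of 7 (pep1 at -6.35) and ethylene genes for 22 and 4 of 38. Their adjusted p-values were 0.0213, 0.0311, 0.0353 and 0.0353, and 0.688, 0.369, 0.364 and 0.412 with an estimated correlation. Potassium transporter genes were higher for 12 and lower for 5 of 19, with HAK24 at 5.58 and HAK10 at 3.37 (adjusted p = 0.0441, and 0.364 with an estimated correlation). Adjusted over the list alone, the counts of these lists were the same. These lists kept the sign of their tests under both other scalings, under which the median of all genes moved from -0.40 to -0.43 and -0.51.

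Root hair differed from both other tissues in many genes. Higher by 2-fold or more than in root and in aerial seedling were 5152 genes, where independent lists would share 1997.6, and 7658 were lower than in both, against 3852.9. In 20 simulations of unchanged groups, 0 genes were called in both comparisons. Part of the excess may come from the shared root hair libraries, and simulations in which no gene differs cannot show how much. The 5152 were out of 25551 genes tested. Among them were 3 of 4 roothairless genes, 11 of 19 potassium transporter genes and 4 of 9 ROP and NADPH oxidase genes. They also held 8 of 25 heat shock genes, such as hsp22, which was at 2.84 against root. Aquaporin genes, with 5 of 27, had a lower share than all genes tested. Against root alone, 9 aquaporin genes were higher and 12 lower (camera adjusted p = 0.745). The 5152 held 0 of 12 expansins, 0 of 13 DNA replication genes, 0 of 9 core histones and 0 of 17 photosynthesis genes by edgeR's quasi-likelihood test.

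Root and aerial seedling of B73 gave the background for the hair comparisons. The root cap gene RCP1 was at least 1102-fold higher in root, where it reached 81.1 ± 3.11 CPM (SD, n = 2). grp3 was higher by 9.93 ± 0.37, the aquaporin genes por2 and TIP2-2 by 9.59 ± 0.39 and 9.32 ± 0.34, and dhs2 by 7.86 ± 0.35 on the log2 scale. Of the roothairless genes, rth3 differed by -0.34 ± 0.22 (adjusted p = 0.189), while GRMZM2G099056, GRMZM2G426953 and GRMZM2G436299 were higher in root by 1.25, 0.87 and 1.54. Of 25551 genes tested with edgeR's quasi-likelihood test, 7293 were higher and 8182 lower in root, 5285 and 6782 of them by 2-fold or more. With upper-quartile scaling the balance turned to 8896 higher and 7145 lower, and the median of all genes moved from -0.02 to 0.20.

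At 0 counts in root, COL8 was at least 955-fold lower, the homeobox gene ocl5 at least 817-fold, TCP7 at least 632-fold and shbp1 at least 584-fold, and the photosystem gene psan1 had 1 count (ratio of aerial seedling to root 9414, interval 1689 to 371870). The peroxidase genes PER66 and PER2 were higher in root by 7.51 and 6.79, NRT1.2 by 1.88 and CesA12 by 1.95, and pht9 had 2 counts in aerial seedling (ratio 266, interval 73.4 to 2200). The actin gene Actin-7, Profilin and rop9 were higher at 2.22, 2.24 and 1.46. expA4, expB7, CesA-5, Agp2, AGP2 and rbohD were lower at -3.77, -3.51, -2.67, -4.11, -2.33 and -2.23. ROP and NADPH oxidase genes were higher for 5 and lower for 1 of 9, actin and vesicle traffic genes for 6 and 2 of 12, and cellulose synthase genes for 5 and 3 of 10 (camera adjusted p = 0.243, 0.19 and 0.534). Without B73 root replicate 2, bHLH7 (-1.30), bHLH84 (-1.15) and GRMZM2G426953 missed the threshold, at adjusted p = 0.0671, 0.148 and 0.0525, and GRMZM2G426953 also without aerial seedling replicate 2, at 0.0766.

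All 17 photosynthesis genes were lower in root, with rbcS-m3 at -12.09 and Cab-m7 at -10.45 (camera adjusted p = 3.67e-10, and 0.317 with an estimated correlation). Pathogenesis-related and chitinase genes were lower for 9 of 10, with PR-5 at -8.63 and chiB at -5.07, benzoxazinoid genes for 9 of 9, with bx2 at -4.66 and bx1 at -2.51, and C4 cycle genes for 6 of 7, with pep1 at -9.56 and rca1 at -11.26. Their adjusted p-values were 4.96e-05, 0.00059 and 0.00168, each 0.317 with an estimated correlation. Peroxidase genes were higher for 5 and lower for 1 of 6 (adjusted p = 0.00482, and 0.339 with an estimated correlation), ap1 at 3.80 among them, and ribosomal protein genes higher for 19 and lower for 3 of 28 (adjusted p = 0.01, and 0.726 with an estimated correlation). Ethylene genes were lower for 22 and higher for 6 of 38, expansins for 9 and 2 of 12 and heat shock genes for 13 and 3 of 25, with adjusted p = 0.0131, 0.0261 and 0.0393, and 0.374, 0.622 and 0.317 with an estimated correlation. DNA replication genes were higher for 9 and lower for 1 of 13 (adjusted p = 0.0498), a call that ended with DESeq2's size factors at 0.051, with upper-quartile scaling at 0.0596, and with an estimated correlation at 0.317. Adjusted over the list alone, the counts of these lists were the same.

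Wild type and zmlrl5 root hair of W22 were compared to find genes that respond to the loss of zmlrl5 in the hair cells. No ID is named LRL5 in the table of names, so the target gene is not analysed here and the labels were not checked by it. Among the roothairless genes, GRMZM2G436299, listed as rth6, was lower in zmlrl5 at 168 ± 22.4 CPM against 275 ± 41.9 CPM (SD, n = 2), a log2 fold change of -0.71 ± 0.10 (SE, adjusted p = 2.62e-06). rth3 differed by -0.03 ± 0.10 (adjusted p = 0.872), GRMZM2G426953 by 0.00 ± 0.08 (adjusted p = 1) and GRMZM2G099056 by 0.23 ± 0.15 (adjusted p = 0.292). NIR, the nitrite reductase gene, went from 111 ± 4.49 to 13.2 ± 1.44 CPM, a log2 fold change of -3.08 ± 0.13 (adjusted p = 7.82e-18). sum1, which makes the siroheme of that enzyme, fell by 4.17 and gln1, a glutamine synthetase gene, by 2.27 on the log2 scale. The nitrate transporter gene nrt2.2, the only called member of the list of nitrate and ammonium transporters, which has 2 tested members and no test, had 3 counts in zmlrl5 and 158 in wild type (ratio of wild type to zmlrl5 45.7, interval 15.4 to 224). bHLH7 had 1 count in zmlrl5 and 47 in wild type (ratio 40.8, interval 6.97 to 1644), so that the zmlrl5 libraries are below the floor of 3 counts.

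Of 25303 genes tested with edgeR's quasi-likelihood test, 2563 were higher and 3140 lower in zmlrl5 root hair, 876 and 1144 of them by 2-fold or more. With all 14 libraries in 1 fit, 1223 were higher and 2010 lower. BURP3, a gene of the BURP-domain family, rose from 1170 ± 5.08 to 4919 ± 197 CPM, a log2 fold change of 2.07 ± 0.07. MRP1, Myb56, MED6.1 and PIP2-4, an aquaporin gene, rose by 2.48, 2.24, 2.23 and 1.88, with standard errors of 0.15, 0.16, 0.17 and 0.08. sfp5 was lower at -5.15 and col-142, a glycine-rich protein gene, at -2.39. Phosphate transporter genes were lower for 2 of 3, pht9 at -0.56 and pht2 at -0.49. Potassium transporter genes were higher for 4 and lower for 4 of 22, HAK21 at 1.72 and HAK9 at -0.98 among them (camera adjusted p = 0.668), and TIP4-3 was lower at -2.24. Expansins were higher for 1 of 9, expB4 at 1.86, and lower for 2, expa1 at -0.86 and expB7 at -1.87, or lower for 4 adjusted over the list alone (camera adjusted p = 0.213). Genes of actin and vesicle traffic were higher for 1 and lower for 5 of 10, with Profilin at -1.46 and Maz63 at -0.95 (adjusted p = 0.213). Peroxidase genes were higher for 1, ap1, and lower for 2 of 7, with PER1 at -1.36 (adjusted p = 0.984, where the median of -0.14 and the test differ in sign). Cellulose synthase genes and their relatives were higher for 4 of 10 (adjusted p = 0.387), and fer1 was higher at 0.52. CesA-7 rose by 0.44, CesA-2 by 0.41, AGP2 by 0.93, rbohB by 0.32 and ap1 by 0.30. Of these 5, CesA-2 missed the threshold without zmlrl5 root hair replicate 1 (adjusted p = 0.0649), AGP2, rbohB and ap1 without wild type root hair replicate 2 (0.137, 0.171 and 0.0878), and AGP2 and rbohB without zmlrl5 root hair replicate 2 (0.0681 and 0.139). With all 14 libraries in 1 fit, CesA-7, CesA-2, rbohB and ap1 were at adjusted p = 0.101, 0.151, 0.325 and 0.352, and without a filter rbohB was at 0.0632.

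Ribosomal protein genes were lower in zmlrl5 root hair for 18 of 27 members and higher for 0, with rps27 at -1.27 ± 0.14, rps12 at -1.02 ± 0.18 and rpl35 at -0.94 ± 0.13. Their list passed camera's test (adjusted p = 1.49e-05, and 0.483 with an estimated correlation). Iron uptake genes were higher for 3 of 6, or 4 adjusted over the list alone: YS3 at 2.36 ± 0.40, AR6 at 0.98 ± 0.11 and ys1, a phytosiderophore transporter gene, at 0.36 ± 0.08 (camera adjusted p = 0.0125, and 0.536 with an estimated correlation). ys1 missed the threshold without zmlrl5 root hair replicate 1, at adjusted p = 0.14, and with all 14 libraries in 1 fit, at 0.193. Aquaporin genes were higher for 10 and lower for 4 of 27, or 11 and 5 adjusted over the list alone, with por2 at 0.90 and PIP1-3 at 1.09 (camera adjusted p = 0.122). Pathogenesis-related and chitinase genes were higher for 5 and lower for 3 of 9, with PR-5 at 1.12, chi1 at 1.05 and chiA at 0.91 (adjusted p = 0.124). Heat shock genes were higher for 5 and lower for 3 of 23, or 7 and 6 adjusted over the list alone, with HSP90-1 at 1.21 (adjusted p = 0.213). Benzoxazinoid genes were lower for 4 and higher for 1 of 9, with bx6 at -3.18 (adjusted p = 0.122). Photosynthesis genes were higher for 7 and lower for 0 of 13, or 9 adjusted over the list alone (adjusted p = 0.0593, and 0.0431 with DESeq2's size factors). That rise came mostly from zmlrl5 root hair replicate 2, without which Cab-m7 went from 1.14 to 0.25 (adjusted p = 0.604), rbcS-m3 from 1.53 to 0.20 (adjusted p = 0.786) and cp29 from 1.37 to 0.40 (adjusted p = 0.433). rbcS-m3 also missed the threshold without wild type root hair replicate 2, at 0.93 (adjusted p = 0.115), and with DESeq2's Wald test (0.222).

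**Figure D3:**
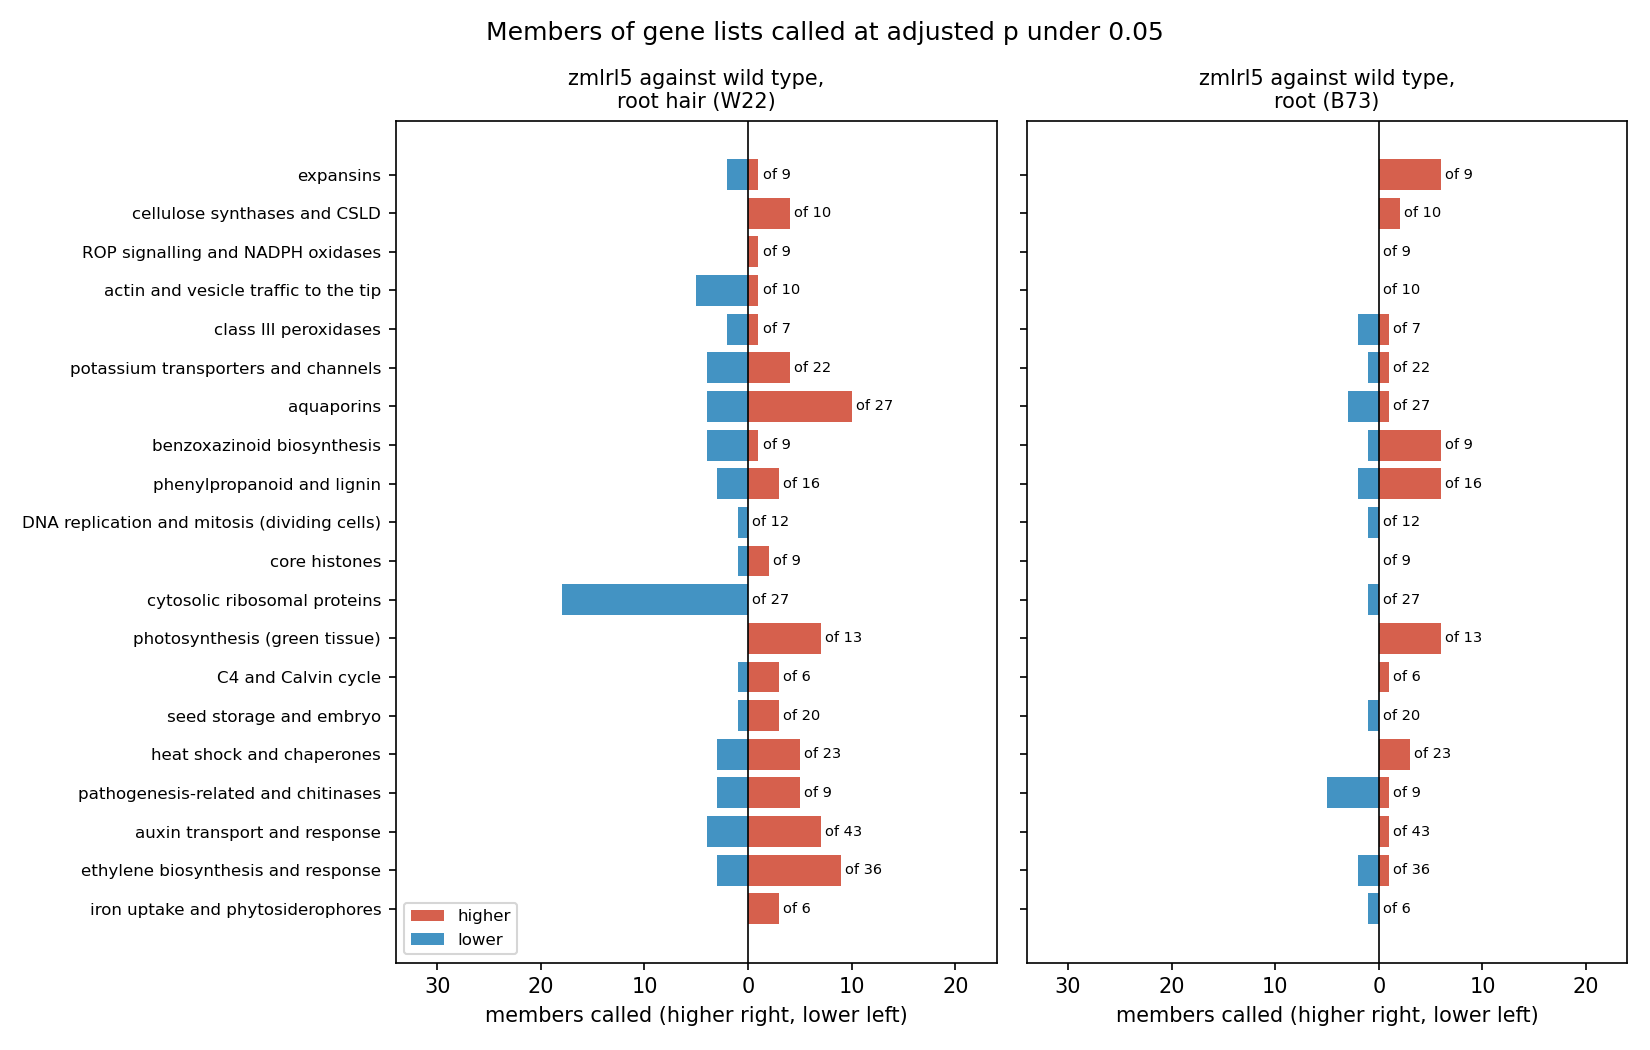
Numbers of members of gene lists (horizontal axis, number of genes) called higher (right) or lower (left) in zmlrl5 against wild type, in W22 root hair and in B73 root, by edgeR's quasi-likelihood test at adjusted p under 0.05. Of 27 cytosolic ribosomal protein genes, 18 are lower in root hair and 1 is lower in root, while 6 of 9 expansins are higher in root.

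Wild type and zmlrl5 root of B73 were compared in the same way. The protocol given for all samples has hairs scraped from roots, but the titles say so for the wild type root libraries of this set and not for the zmlrl5 ones. GRMZM2G436299, listed as rth6, had 0 counts in both zmlrl5 libraries and 96 in wild type, at least 41.3-fold lower. Its effect in W22 root hair was weaker by 7.82 on the log2 scale (interaction test, adjusted p = 1.02e-07), a size that depends on the prior count. rth3 differed by -0.02 ± 0.12 (adjusted p = 0.975), GRMZM2G099056 by -0.07 ± 0.13 (adjusted p = 0.884), bHLH7 by 0.47 ± 0.19 (adjusted p = 0.166, but 0.44 with adjusted p = 0.023 with only the libraries compared, and 1.43 with adjusted p = 1.98e-05 with both sets of wild type B73 root libraries) and GRMZM2G426953 by 0.29 ± 0.10 (adjusted p = 0.0596, but 0.0159 without zmlrl5 root replicate 2, 0.0327 with only the libraries compared and 0.0493 with a filter of 1 CPM). Cel4, at 5061 CPM in B73 root hair of the tissue set, fell from 36 ± 1.03 to 0.463 ± 0.113 CPM (SD, n = 2), a log2 fold change of -6.27 ± 0.16 (SE, adjusted p = 3.24e-23). PER2 fell from 468 ± 26.8 to 131 ± 0.506 CPM, a log2 fold change of -1.84 ± 0.07 (adjusted p = 2.11e-19). The fatty acid desaturase gene fad2 rose from 3.82 ± 0.00995 to 33.6 ± 0.897 CPM, a log2 fold change of 3.14 ± 0.16.

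Of 25303 genes tested with edgeR's quasi-likelihood test, 1081 were higher and 1034 lower in zmlrl5 root, 284 and 420 of them by 2-fold or more. The balance turned to 965 higher and 1070 lower with DESeq2's size factors and to 1030 and 1150 with upper-quartile scaling. The 2115 calls became 1133 without wild type root replicate 1 (440 higher, 693 lower), 1235 without wild type root replicate 2 (664 and 571), 1261 without zmlrl5 root replicate 1 (504 and 757) and 1453 without zmlrl5 root replicate 2 (837 and 616). Phosphate transporter genes were lower for 3 of 3, pht2 at -1.72 ± 0.10, pht9 at -1.60 ± 0.13 and pht1 at -0.38 ± 0.09, and pht1 missed the threshold with all 14 libraries in 1 fit (adjusted p = 0.408) and without wild type root replicate 2 (0.279), zmlrl5 root replicate 1 (0.0865) or zmlrl5 root replicate 2 (0.0645). Markers of root hair were lower in the same libraries: 131 genes at least 64-fold higher in B73 root hair than in root, a set chosen after the results were seen, had a median log2 fold change of -2.04, with 93 called lower and 0 higher by edgeR. CYP71Z16 and CPPS2, genes of diterpenoid defence compounds, fell by 1.73 and 1.58 on the log2 scale. With both sets of wild type B73 root libraries, which brings in differences between the sets, CYP71Z16 was at 0.51 and pht1 at 0.74. HAK1 at -0.87, the proton pump gene mha4 at -0.44 and BX14 at -1.91 were lower. The dehydrin gene dhn1 at 1.82, the lignin genes ccr2 and Laccase-13 at 1.48 and 1.03, bx1 at 0.83 and the silicon transporter gene Lsi6 at 2.26 were higher. bx1 missed the threshold with DESeq2's Wald test (adjusted p = 0.117), and mha4 with all 14 libraries in 1 fit (0.103). Small changes were CesA12 at 0.33, CesA-7 at 0.28, AGP2 at 0.52, PER70 at 0.42, pcna1 at -0.43, RPL10 at -0.38 and sip1 at -0.53. Their lists had 2 cellulose synthase genes higher of 10 (camera adjusted p = 0.0577), 1 peroxidase gene higher and 2 lower of 7 (0.179), 1 replication gene lower of 12 (0.205) and 1 aquaporin gene higher and 3 lower of 27 (0.663, where the median of 0.02 and the test differ in sign). Adjusted over the list alone, 3 cellulose synthase genes were higher, 3 peroxidase genes lower, and 3 aquaporin genes higher and 7 lower. With all 14 libraries in 1 fit, these 7 were at adjusted p = 0.188 to 0.531. AGP2 and pcna1 were at 0.24 and 0.144 with DESeq2's Wald test. CesA12, CesA-7 and pcna1 were at 0.0559, 0.108 and 0.0503 without a filter, and CesA12 and PER70 at 0.374 and 0.129 with both sets of wild type B73 root libraries. Without wild type root replicate 1, the first 6 of these were at adjusted p = 0.197, 0.143, 0.103, 0.0748, 0.376 and 0.103. Without wild type root replicate 2, CesA-7, AGP2, pcna1 and sip1 were at 0.073, 0.396, 0.17 and 0.115. Without zmlrl5 root replicate 1, CesA12, AGP2 and pcna1 were at 0.192, 0.0938 and 0.449, and without zmlrl5 root replicate 2, CesA-7, AGP2, pcna1 and sip1 were at 0.137, 0.403, 0.14 and 0.0775.

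Expansin genes were higher in zmlrl5 root for 6 of 9 members and lower for 0, with expB7 at 1.36 ± 0.09, expa1 at 1.22 ± 0.09, expB6 at 1.09 ± 0.08 and expB3 at 0.70 ± 0.09. Their list passed camera's test (adjusted p = 9.02e-05, and 0.382 with an estimated correlation). Photosynthesis genes were higher for 6 of 13, with Cab-m7 at 5.35 ± 0.49, cp29 at 4.05 ± 0.38 and psah1 at 2.57 ± 0.34 (adjusted p = 9.02e-05, and 0.529 with an estimated correlation), though rbcS-m3 differed by 0.49 (adjusted p = 0.635). Pathogenesis-related and chitinase genes were lower for 5 and higher for 1 of 9, with chitinase2 at -2.21, chiA at -1.33, PR-5 at -0.86 and chi1 at 0.48 (adjusted p = 0.00438, and 0.405 with an estimated correlation). PR-5 was at -0.11 (adjusted p = 0.686) with both sets of wild type B73 root libraries, and chi1 at adjusted p = 0.29 with all 14 libraries in 1 fit. Root cap genes were lower for 2 of 2, with rc123A at -3.82 ± 0.41. RCP1 had 3 counts against 17 (ratio of wild type to zmlrl5 7.31, interval 2.12 to 38.9). In B73 root of the tissue set RCP1 had 4754 counts, so it was already low in wild type root here. Whether both sets took the same part of the root was not tested. RCP1 missed the threshold without wild type root replicate 1 (adjusted p = 0.0558) or zmlrl5 root replicate 2 (0.0717). Benzoxazinoid genes were higher for 6 of 9, with bx2 at 0.68, and lower for BX14 (adjusted p = 0.12). Lignin genes were higher for 6 of 16, or 8 adjusted over the list alone, and lower for 2, the laccase genes lac3 and LAC1 (GRMZM2G400390) (adjusted p = 0.0934). Heat shock genes were higher for 3 of 23, with Hsp70 at 0.66 and HSP90-1 at 0.58 (adjusted p = 0.0637). With both sets of wild type B73 root libraries, which brings in differences between the sets, Hsp70 was at -0.41 and HSP90-1 at -0.50. Ribosomal protein genes were lower for 1 of 27, RPL10 (adjusted p = 0.052, 0.0452 with DESeq2's size factors and 0.0432 with upper-quartile scaling).

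**Figure D4:**
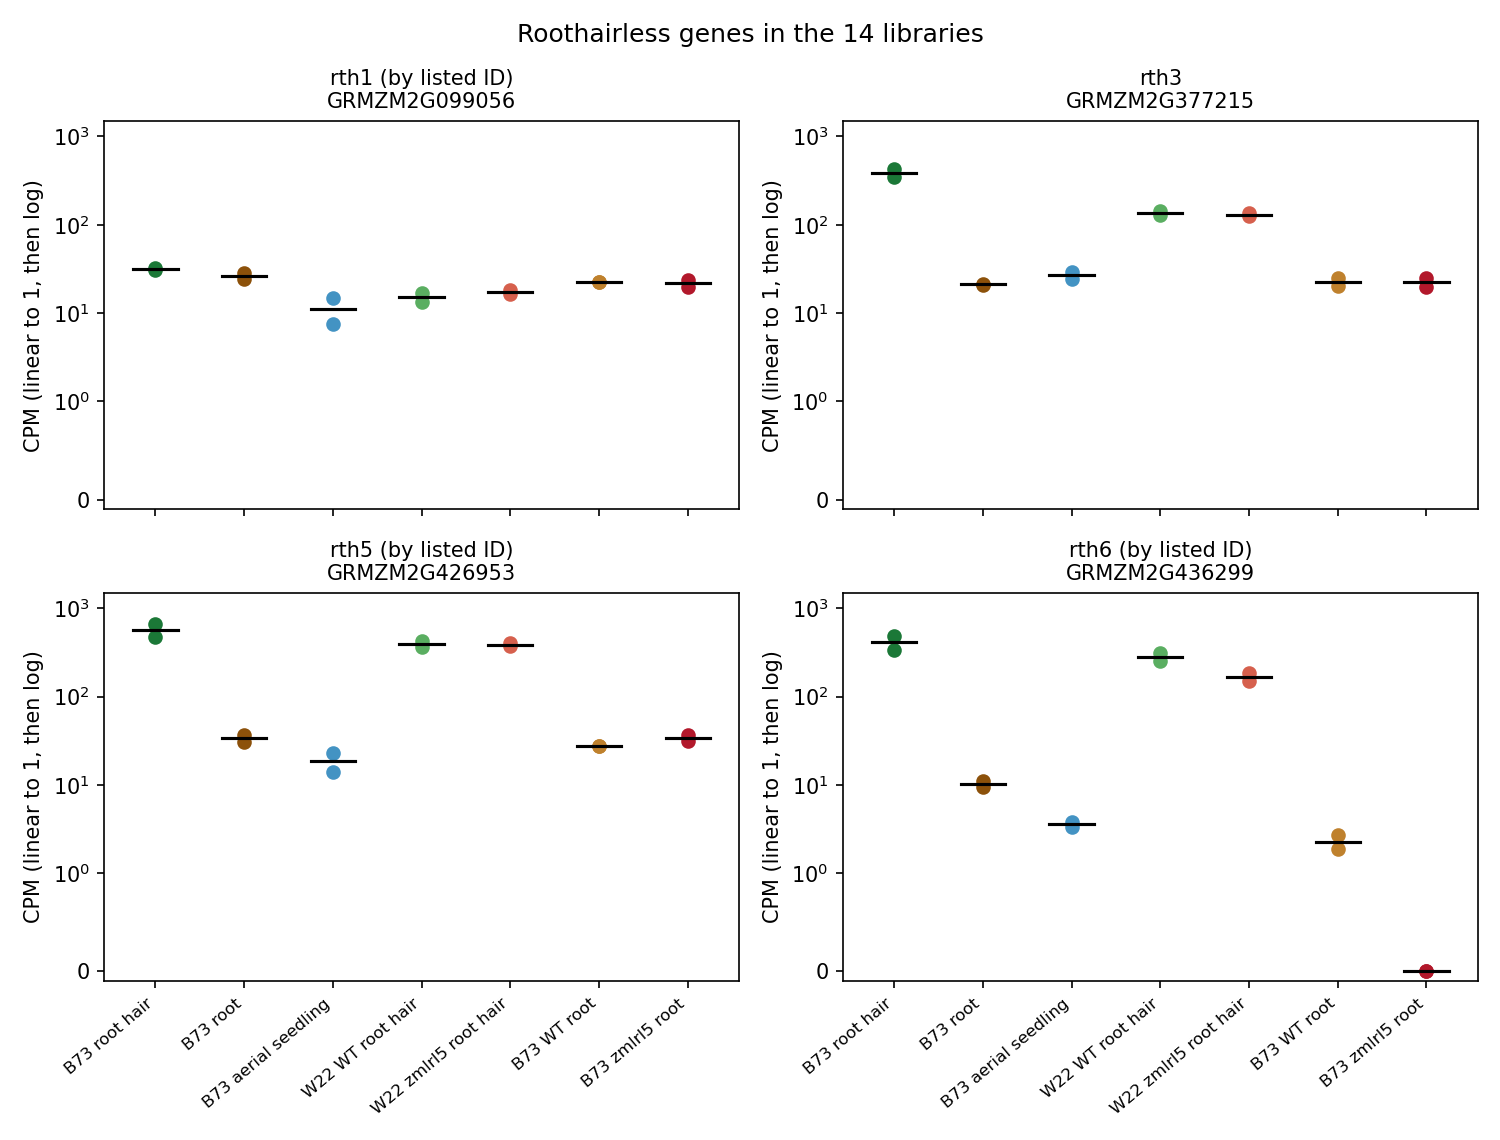
CPM of the 4 roothairless genes in each library (points) with the mean of each group (line), on an axis that is linear up to 1 and logarithmic above, scaled over all 14 libraries, so that values differ slightly from those of each set's own fit. GRMZM2G436299 is at 486 and 339 in B73 root hair, 1.86 and 2.68 in B73 wild type root of the zmlrl5 set, and 0 in both zmlrl5 root libraries.

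The mutant effects in W22 root hair and in B73 root were compared gene by gene. Ribosomal protein genes fell further in zmlrl5 root hair than in root, with adjusted p = 0.00343 for the difference by camera (adjusted p = 0.315 with an estimated correlation). The same test gave adjusted p = 0.0111 for expansins, which were higher in zmlrl5 root. It gave 0.00607 for pathogenesis-related and chitinase genes and 0.00343 for iron uptake genes, each 0.315 with an estimated correlation. Of 25303 genes tested with edgeR's quasi-likelihood interaction test, 1650 had a higher and 2051 a lower log2 fold change in root hair than in root, or 728 and 1100 with all 14 libraries in 1 fit. Tissue, inbred line and allele change together here. Of the genes called in both, 366 were lower in both where independent lists would share 128.3 (odds ratio 4.25, 95% interval 3.7 to 4.86, Fisher's exact p = 3.17e-85), and 276 were higher in both against 109.5 (odds ratio 3.29, Fisher's exact p = 5.64e-50). Lower in root hair and higher in root were 171 genes against 134.1 (odds ratio 1.35, Fisher's exact p = 0.000798), and the opposite held for 152 against 104.7 (odds ratio 1.56, Fisher's exact p = 2.55e-06). Overlaps of opposite direction thus also exceeded independent lists, and these tests count genes as independent. Among changes of 2-fold or more these opposite overlaps missed the threshold, with odds ratios of 1.52 and 0.961 (Fisher's exact p = 0.0835 and 1).

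Genes changed in zmlrl5 root hair were set against genes that differ between root hair and root in B73, over 23505 genes tested in both. Of the genes lower in zmlrl5 root hair, rth6's ID, pht9, pht2 and TIP4-3 were also higher in B73 root hair than in root. In all, 1386 genes were lower in zmlrl5 and higher in root hair, where independent lists would share 1102.7 (odds ratio 1.56, 95% interval 1.44 to 1.69, Fisher's exact p = 1.95e-29). Among changes of 2-fold or more this turned round, with 242 genes against 312.3 (odds ratio 0.7, Fisher's exact p = 8.88e-07). Genes lower in both numbered 1201 against 1200.6 (odds ratio 1, Fisher's exact p = 0.984), but 664 against 389.1 among changes of 2-fold or more (odds ratio 2.97, Fisher's exact p = 2.41e-67). Genes higher in zmlrl5 were higher in root hair for 1050 against 881.4 (odds ratio 1.38, Fisher's exact p = 1.25e-13) and lower for 849 against 959.7 (odds ratio 0.806, Fisher's exact p = 1.22e-06). Both turned round among changes of 2-fold or more, to odds ratios of 0.778 and 1.94 (Fisher's exact p = 0.00265 and 1.64e-19).

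Wild type libraries of the 2 sets were compared over 27316 genes in a fit of all 14 libraries. rth3 stood at 426 and 346 CPM in the B73 root hair libraries and at 129 and 144 CPM in the W22 ones, and GRMZM2G436299 at 9.55 and 11.1 CPM in B73 root of the tissue set and at 1.86 and 2.68 CPM in that of the zmlrl5 set. edgeR's quasi-likelihood test called 7679 genes higher and 7072 lower in W22 than in B73 root hair, with inbred line and library set confounded. Between the B73 wild type root libraries of the 2 sets, which share line, tissue and genotype in the labels, it called 7486 genes higher and 6039 lower in the zmlrl5 set. The balance turned to 6233 higher and 6921 lower with DESeq2's size factors, where the median of all genes moved from 0.11 to 0.00, and to 5649 and 6332 with DESeq2's Wald test. Levels were therefore mostly compared within a set elsewhere. Exceptions are the levels of Cel4 and RCP1 beside zmlrl5 root, the share of root hair material, and the fits with both sets of wild type root libraries.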

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

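All tests of explanations here were chosen after the results they bear on had been seen, while the interaction test was planned. The interaction test of edgeR set the zmlrl5 effect in W22 root hair against that in B73 root and called 3701 genes, with tissue, line and allele changing together. Differences of log2 fold changes, root hair minus root, were 2.53 for MRP1, 2.32 for Myb56, 2.14 for MED6.1, 1.85 for BURP3, 1.76 for PIP2-4, 0.54 for fer1, 0.66 for ap1, 1.04 for pht9, 1.22 for pht2, 0.61 for HAK1, 0.66 for sip1 and 1.20 for BX14. They were 5.97 for Cel4, 1.65 for PER2, 2.09 for CYP71Z16 and 2.81 for CPPS2. Negative differences were -4.15 for sum1, -3.44 for NIR, -1.71 for gln1, -6.28 for sfp5, -2.07 for expa1, -3.23 for expB7, -1.80 for Profilin, -1.40 for PER1, -1.13 for HAK9, -3.66 for fad2, -0.94 for ccr2, -1.89 for Laccase-13 and -4.21 for Cab-m7. With counts of 0 or near 0 in some groups, GRMZM2G436299 at 7.82, HAK21 at 6.33 and bHLH7 at -5.57 have sizes that depend on the prior count. The interaction was not called for rth3 (adjusted p = 1), GRMZM2G099056 (0.369), GRMZM2G426953 (0.139), col-142 (0.334), TIP4-3 (0.747), CesA-2 (0.173), rbohB (0.531), Maz63 (0.121), CesA12 (0.3), PER70 (0.815), Lsi6 (0.831), bx1 (0.16), pcna1 (0.104) or RPL10 (0.474). Gene lists differed by camera at adjusted p = 0.0111 for expansins, 0.00343 for ribosomal proteins, 0.00607 for pathogenesis-related and chitinase genes and 0.00343 for iron uptake, each at adjusted p = 0.315 with an estimated correlation. Reads outside genes, which enter no comparison, made up 6.34% and 6.71% in the B73 root hair libraries, above the 4.14% and 4.42% in B73 root and the 3.69% and 3.58% in aerial seedling.

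Genes lower in zmlrl5 root of B73 were mostly genes higher in root hair than in root, 649 of 1016 or 63.9%, against 34.6% of the other genes (odds ratio 3.34, 95% interval 2.93 to 3.82, Fisher's exact p = 1.25e-76). Genes that mark root hair fell there. The 131 genes at least 64-fold higher in root hair had a median log2 fold change of -2.04 (quartiles -4.68 to -0.59). BX14 (1.67 in root hair against root) and pht2 (2.01) were at -1.91 and -1.72, and GRMZM2G436299 had 0 counts in zmlrl5. In contrast, rth3 (4.21) was at -0.02 and GRMZM2G426953, also higher in root hair, at 0.29. Both are also read in root without hairs, so the fall that lost hair would give them depends on the share lost. These single genes decide nothing about the cause here. The share of root hair material that the 131 genes allow was, at its 90th percentile, 1.11% with B73 and 3.81% with W22 root hair levels. Of the 649 genes, 525 and 406 fell by more than that share could take away. Independent lists would already share 364.3 genes, and the zmlrl5 set holds no B73 root hair library. These counts therefore cannot exclude less root hair material as the cause of the excess. No single root library of the zmlrl5 set decides the overlap, as the lowest odds ratio with 1 of them left out was 3.93. Libraries of the tissue set were not left out for this. Part of the fall could still come from less hair material, through genotype or closer scraping of zmlrl5 roots. The titles mention scraping for the wild type root samples of this set alone. Taken literally, they would leave more hair in zmlrl5 root, the opposite of the fall. Lower transcript levels in zmlrl5 were not tested apart from less hair material.

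Genes lower by 2-fold or more in zmlrl5 root hair of W22 were mostly genes lower in root hair than in root, 664 of 1088 where 389.1 would be shared by independent lists (odds ratio 2.97, 95% interval 2.62 to 3.37). Less root tissue in the scraped zmlrl5 fraction would lower root markers together, which was not seen. The 167 genes at least 64-fold lower in root hair had a median of -0.06 (quartiles -0.77 to 0.68), with 27 called lower and 30 higher. For these genes the values argue against less root tissue as the whole cause. They do not exclude it, as the markers come from B73 root and the zmlrl5 set holds no W22 root library. Genes higher by 2-fold or more were likewise often lower in root hair, 404 of 788 against 281.8 (odds ratio 1.94, Fisher's exact p = 1.64e-19), so the overlap is not particular to lower genes. No single W22 root hair library decides the overlap of the lower genes, with a lowest odds ratio of 2.37 when 1 was left out. Tissue set libraries were not left out for this. Without the limit of 2-fold, the odds ratios were 1 for lower and 0.806 for higher genes. The overlap thus came with the limit in both directions, and the reason was not tested. A response of W22 root hair to zmlrl5 remains possible and was not tested apart from the limit, line and allele.

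Genes changed by 2-fold or more in zmlrl5 root hair lay close together along the B73 assembly, with 18 in the fullest run of 50 neighbouring genes, 8 higher and 10 lower, against a median of 12 and a maximum of 17 in 1000 shuffles. Chromosome segments that differ between the zmlrl5 and wild type plants could give this, by a narrow margin. Shared expression of neighbours in any comparison cannot be told apart from it, as root hair against root gave 3418 adjacent pairs of the same direction against 3266.4 shuffled, a ratio of 1.05, and zmlrl5 root hair 70 against 50.7, a ratio of 1.38. Neighbours that change together in any comparison of zmlrl5 with wild type cannot be told apart from it either, as zmlrl5 root had 6 in its fullest run against a shuffled median of 6, but 13 adjacent pairs against 4.2. The run in zmlrl5 root was counted after its adjacent pairs had been seen.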

How the results depend on the processing

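Of counts of called genes under the alternatives, 102 stayed within 1.5 times the value reported. In zmlrl5 root the count moved to 955 with all 14 libraries in 1 fit, 3701 with only the libraries compared and 8332 with both sets of wild type root libraries (5182 higher and 3150 lower), and ran from 1133 to 1453 with 1 library left out. The 14-library fit gave 3233 for zmlrl5 root hair and 1828 for the interaction. A library left out leaves fewer samples by construction, with the lone library assumed to vary like the other groups. With both wild type root sets, zmlrl5 root is set against the mean of both, so differences between the sets enter. Between those wild types, 13525 of 27316 genes were called. The 14-library fit had a larger common coefficient of variation between libraries, 0.14 against 0.08 in the zmlrl5 set's fit. How much of its shift this gives, and the cause of the other shifts, was not tested. Limited to changes of 2-fold or more, the overlaps of zmlrl5 root hair with root hair against root went to odds ratios of 0.7 (lower, higher), 0.778 (higher in both) and 1.94 (higher, lower), which reversed, and 2.97 (lower in both), which became stronger. Of those with opposite directions in zmlrl5 root hair and root, the odds ratios of 1.35 and 1.56 went to 1.52 and 0.961, and both lost the threshold (Fisher's exact p = 0.0835 and 1), with 19 and 14 genes left. Called lists numbered 0 in each of 6 comparisons with an estimated correlation, an option that also leaves few degrees of freedom. With fry they numbered 16 for root hair against root and 10 for zmlrl5 root hair. With both wild type root sets, CYP71Z16 at 0.51, pht1 at 0.74, Hsp70 at -0.41 and HSP90-1 at -0.50 reversed. Values of the genes named by the rule stayed the same in 1804 cases, with 50 no longer past the threshold, 5 newly past it and 1 reversed. Other list members stayed the same in 1002, with 15 no longer past it, 3 newly past it and 3 reversed. Replicate numbers shared no pattern (correlations -0.17 to 0.09), and as a block they gave 18230 genes for root hair against root, 19846 and 14722 for root hair and root against aerial seedling, 5152 and 1792 for zmlrl5 root hair and root, and 3286 for the interaction. Depth limits genes near the floor of 3 counts.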

Other observations

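W22 wild type root hair and B73 wild type root of the zmlrl5 set were compared after the data were seen, with inbred line and tissue confounded. edgeR's quasi-likelihood test called 9225 genes higher and 11135 lower in root hair. Of 17606 genes called between B73 root hair and root and tested here, 14452 or 82.1% had the same sign, 12842 were called with the same sign and 2072 with the opposite sign. Of 5034 genes higher in B73 root hair than in root and aerial seedling, 3713 were higher here and 608 lower.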
